A study of Homo sapiens with 6 samples.

How the data were processed

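Gene expression was measured in 6 K562 cultures, 3 with the miR-92a-1-5p mimic and 3 with the negative-control mimic, all with imatinib. Groups, replicate numbers and doses were taken from the sample labels, and table columns were matched to samples by the column names the labels give. Per the labels' protocols, total RNA was sequenced as read pairs, with an average coverage of 62 M, and quantified by the authors with kallisto. The version, transcript annotation, library strand and the step from transcripts to genes were not given in the sources used here.

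The values are expected counts, that is estimated counts of reads per gene symbol that the authors made with kallisto, deposited as whole numbers and not scaled to a common total. GRCh38 is the build the labels name. The table held 35615 symbols, of which 12102 were 0 in all libraries, and all per-sample columns were used. Totals were 25.4, 25.4 and 24.8 M for scramble 1, 2 and 3 and 0.704, 26.0 and 25.6 M for miR92a 1, 2 and 3. The median count of tested genes was 16 in miR92a 1, for a Poisson coefficient of variation of 25%, and 556 to 613 elsewhere, for 4.04% to 4.24%. Mitochondrially encoded genes held 8.71% to 11.2% of the counts.

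Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr (14543 kept), scaled by TMM and tested with the quasi-likelihood F-test on group alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM values are TMM-scaled, and log2 values for structure checks used a prior count of 2. The test, the gene lists, the seed test and the alternatives were fixed before the data were examined, except those named below as added. The rule for named genes was also fixed then: the 12 largest falls and 8 largest rises among genes past the threshold, with a mean of at least 2 CPM and no overlap between groups, then per list up to 4 members past the threshold, or where none passed up to 2 with the highest mean CPM, as values. Other genes are said to have been chosen after the values were seen.

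Each of 30 gene lists with at least 5 members measured was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list and with fry. Members were counted after adjustment over all genes and over the list alone.

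Seed matches were sought in the longest 3′ UTR of each gene in GENCODE v29 as the 6mer CCAACC, the 7mers CCCAACC and CCAACCA and the 8mer CCCAACCA for miR-92a-1-5p, and as TGCAAT, GTGCAAT, TGCAATA and GTGCAATA for miR-92a-3p. Of the tested symbols 13672 matched the annotation, 871 did not, and 12889 (88.6%) had a 3′ UTR. Site genes were tested with camera and compared with genes matched on 3′ UTR length, or length and GC content, with 2000 bootstrap draws over genes; camera on the same matched genes was added after the counts were seen. They were also compared with up to 1000 random seeds whose number of genes lay within 20%. Coding sequences were searched in the same way among genes with no 6mer in the 3′ UTR. Shares among called genes were compared with Fisher's exact test, adjusted over 16 tests, and, in a comparison added after the counts were seen, with the shares of random seeds. These steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9. The isoforms K562 cells use were not measured.

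Whether the replicate numbers pair the cultures was checked from the counts, since the labels do not say: deviations from group means correlated between same-numbered libraries at 0.37, 0.48 and 0.63 over the 4829 genes with a mean of at least 1000 counts, and at 0.15, 0.16 and 0.42 over all tested genes. Scramble 1 correlated more with miR92a 2 (0.52) than with miR92a 1 over the abundant genes, so the numbers set replicate 3 apart but not replicates 1 and 2 from each other. Since each same-numbered pair had a correlation over 0.1, the fit with the replicate number as a block is given beside the fit without it. The swapped pairs of replicates 1 and 2 also passed this rule over the abundant genes (0.52 and 0.25), so it does not show pairing beyond replicate 3. Library differences were summarised as a chi-square per gene over genes with a summed count of at least 50.

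The alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, median-of-ratios scaling, total counts alone, no filter, a mean of at least 1 CPM, a test against a fold of 1.2, protein-coding genes alone, the replicate block, and each library left out in turn. Added after the counts were seen were the block with each pair left out, replicates 1 and 2 alone, replicate 3 as a batch term, and binomial thinning of all libraries to the depth of miR92a 1. The code was tested on simulated data (14269 genes tested) with the depths of these libraries: the fit without the block recovered 22.7%, 60.6% and 86.2% of genes changed by a fold of 1.5, 2 and 4, and 10.4% of its calls were unchanged genes. The blocked fit recovered 24.2%, 63.6% and 83.1%, with 11.0% unchanged genes among its calls. Both shares of unchanged genes lay above the adjusted p threshold of 0.05. In the simulated data the fits recovered similar shares, whereas in the real counts the block called 1639 genes against 205 without it. The check therefore cannot show how the blocked fit behaves on these libraries, and the share of unchanged genes among its calls there is not known. The level of either microRNA strand and protein levels were not analysed here. Values of some single list members are not reported here.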

Results

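The series measured gene transcripts by paired-end sequencing of total RNA in K562 cells, a human erythroleukaemia line derived from chronic myeloid leukaemia in blast crisis that carries the BCR-ABL1 fusion kinase. Per the labels, 5 M cells were nucleofected with 500 pmol of a synthetic mimic of hsa-miR-92a-1-5p, the strand of the miR-92a-1 hairpin that usually accumulates less than its partner miR-92a-3p, or with a negative-control mimic. Imatinib, an inhibitor of the ABL1, KIT and PDGFR tyrosine kinases, was added to 1 µM in all cultures 4 h after transfection, and RNA was taken 24 h later. The table held 3 libraries per group (miR92a 1 to 3 and scramble 1 to 3), all labelled as biological replicates; cultures without imatinib or without a mimic were not analysed here. Library totals lay between 24.8 and 26.0 M counts in 5 libraries, but miR92a 1 held 0.704 M (704448 counts), 36.0-fold less than the median of the other libraries. In that library 40.3% of the 14543 tested genes had fewer than 10 counts, against 1.89% to 2.52% in the others, and 3 counts stood for 4.26 CPM there and for 0.115 to 0.121 CPM elsewhere.

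The comparison asked which transcripts were lowered by the miR-92a-1-5p mimic in imatinib-treated K562 cells, the question the series title names. With the mimic 142 genes were lower and 63 were higher (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 libraries per group). The largest fall was that of SLC25A23, a calcium-regulated mitochondrial ATP-Mg/phosphate carrier (chromosome 19, 6436079 to 6465203, GRCh38), from 118 ± 4.11 to 22.6 ± 4.72 CPM (mean ± SD, n = 3), a log2 fold change of -2.31 ± 0.14 (SE, adjusted p = 8.7e-04). PUDP, a pseudouridine monophosphate phosphatase on chromosome X (7048920 to 7148190), fell from 50.6 ± 0.325 to 13.3 ± 0.838 CPM, and the class I myosin MYO1D (chromosome 17, 32492522 to 32877177) from 145 ± 7.50 to 39.6 ± 5.99 CPM, with log2 fold changes of -1.94 and -1.88. All 142 lower and all 63 higher genes had non-overlapping values in the 2 groups, a pattern shown by 21.2% of all tested genes where 10% is expected by chance for 3 against 3.

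The other 9 of the 12 largest falls follow. TMEM50A, a small membrane protein, had a log2 fold change of -1.79 ± 0.12 (SE). The glycolipid transfer protein GLTP changed by -1.70 ± 0.28, on only 3 counts in miR92a 1. VCL, which encodes the focal-adhesion protein vinculin, fell from 351 ± 56.3 to 110 ± 23.6 CPM (-1.67 ± 0.18), and DAG1, the dystroglycan receptor for extracellular matrix, fell by 1.47 ± 0.13 on the log2 scale. The protein-crosslinking enzyme TGM2 changed by -1.65 ± 0.24, the protein phosphatase methylesterase PPME1 by -1.58 ± 0.11 and the aminoacylase ACY1 by -1.58 ± 0.18. PA2G4, a growth-related RNA-binding protein, was the most abundant of the 12, at 529 ± 49.7 CPM in the control libraries and 188 ± 31.5 with the mimic (-1.52 ± 0.14, adjusted p = 0.0023); it has processed pseudogenes with which reads can be shared. BNIP3L, a mitophagy receptor of the BCL2 family used in erythroid maturation, changed by -1.49 ± 0.23, and its decrease was larger in the replicate 3 pair (-1.98) than in the replicate 1 and 2 pairs (-1.03 and -1.20). With libraries left out 1 at a time, GLTP passed only without scramble 3 (adjusted p up to 0.131 without the others). VCL missed the threshold without miR92a 1 (0.0511), TGM2 without scramble 2 (0.0523) or miR92a 1 (0.104), and BNIP3L without any mimic library (0.0711 to 0.113).

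The 8 largest rises follow. PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis (chromosome 11, 47565430 to 47573461), rose from 8.61 ± 0.956 to 26.5 ± 0.948 CPM, a log2 fold change of 1.63 ± 0.15 (SE, adjusted p = 0.0024). PDIA4, a protein disulfide isomerase of the endoplasmic reticulum, rose by 1.49 ± 0.28 and CALU, a calcium-binding protein of the secretory pathway, by 1.04 ± 0.17. BANF1, a chromatin-binding protein of nuclear envelope assembly, rose from 59.2 ± 6.92 to 156 ± 14.0 CPM (1.41 ± 0.12). NSMF changed by 1.18 ± 0.13, TOMM20, a receptor of the mitochondrial import machinery, by 0.95 ± 0.08, and MAP2K4, a kinase upstream of JNK and p38, by 0.93 ± 0.15. H3F3AP4 (1.73 ± 0.30) is annotated as a processed pseudogene of a histone H3.3 gene and TOMM20 has processed pseudogenes, so reads of either can be shared with near-identical copies and their values are uncertain. Calls were lost for PDIA4 without each library except scramble 3 (adjusted p up to 0.138), for CALU without scramble 1, scramble 2, miR92a 1 or miR92a 2 (up to 0.126), for MAP2K4 without scramble 1, scramble 2 or miR92a 2 (up to 0.128), and for H3F3AP4 without scramble 1, scramble 3, miR92a 1 or miR92a 3 (up to 0.128).

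**Figure D1:**
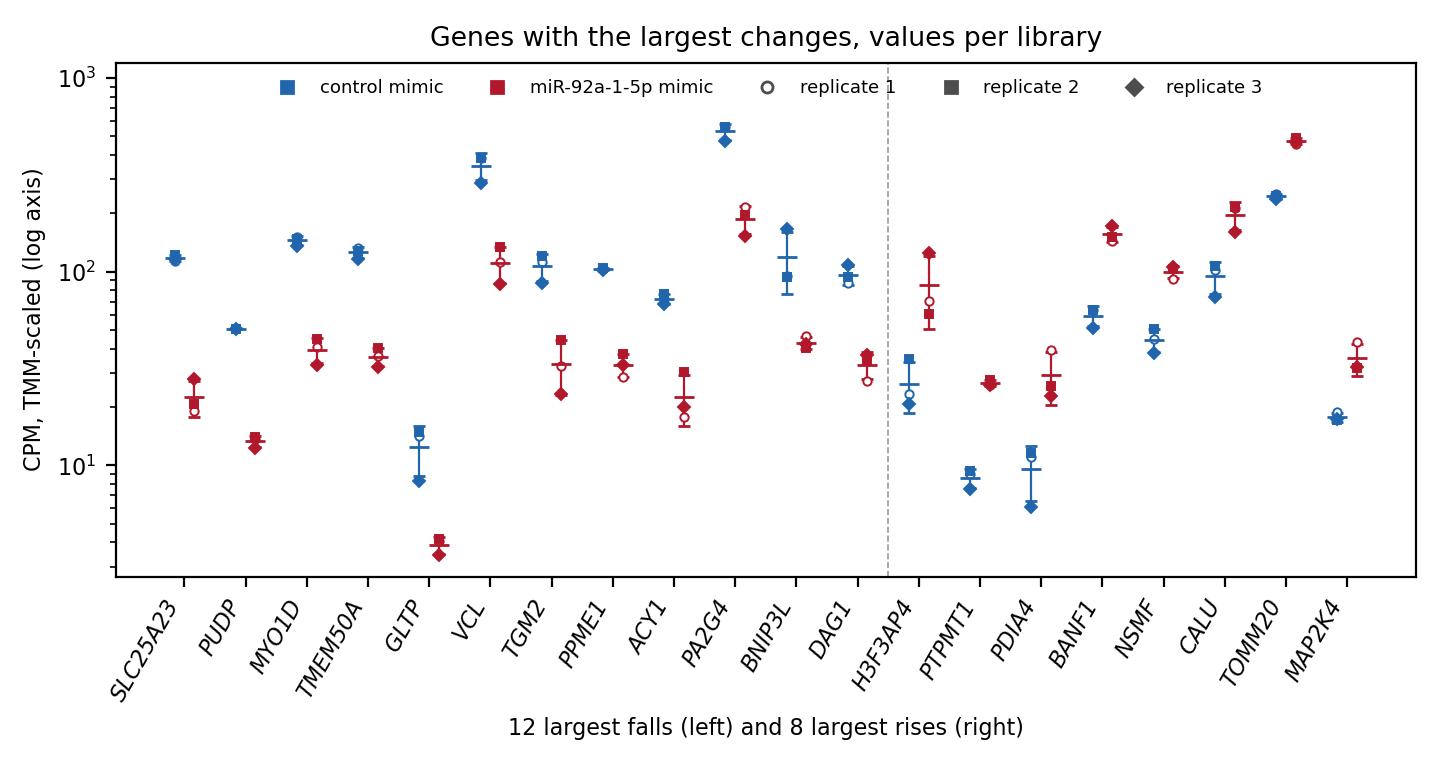
CPM (TMM-scaled, log axis) of the 12 genes with the largest falls and the 8 with the largest rises in each of the 3 control-mimic (blue) and 3 miR-92a-1-5p mimic (red) libraries; symbols mark the replicate number, open circles replicate 1, and bars the mean ± SD. The values of each gene do not overlap between the groups; SLC25A23 has the largest fall (log2 fold change -2.31).

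The count of changed genes depended on the model. With the replicate number as a block, 975 genes were lower and 664 higher, among them all 205 genes called without it. Counts of list members below stand against these shares of all genes. With the block 1639 of the 14543 tested genes passed, and without it 1964 had an unadjusted p under 0.05. Without the block, leaving out scramble 1 gave 57 lower and 15 higher genes, scramble 2 gave 56 and 14, scramble 3 gave 148 and 53, miR92a 1 gave 59 and 18, miR92a 2 gave 61 and 19, and miR92a 3 gave 88 and 41. All 205 genes kept their direction in each of these fits. Their non-overlapping groups and equal sign in all 3 pairs fixed this outcome, so it does not measure stability.

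Genes with a match to the miR-92a-1-5p seed in the 3′ UTR were lower with the mimic than genes without one. The seed, bases 2 to 8 of the strand, pairs with CCCAACC, and 2173 of the 12889 tested genes with an annotated 3′ UTR held a 7mer or 8mer match. Their median log2 fold change was -0.13, against 0.01 for the 10716 genes without one, a difference of -0.14 (limma's camera test with a preset correlation of 0.01, p = 3.7e-09; p = 3.5e-04 with an estimated correlation). Each mimic library gave such a difference against the mean of the control libraries (-0.14, -0.13 and -0.16 for miR92a 1, 2 and 3). The medians were -0.19 for the 390 genes with an 8mer (CCCAACCA), -0.116 for the 1108 genes with at best a 7mer-m8, -0.122 for the 675 with a 7mer-A1 (CCAACCA), -0.05 for the 1321 with a 6mer alone and 0.02 for the 9395 with none. Genes with 1 site had a median of -0.11 and the 333 genes with 2 sites one of -0.21, close to that of the 108 genes with 3 or more sites. Genes with a site had longer 3′ UTRs (median 2660 against 1136 bases). Against genes without a site matched on 3′ UTR length the difference was -0.10 (95% bootstrap interval -0.12 to -0.07), and matched on length and GC content it was -0.13 (-0.15 to -0.11). None of 1000 random seeds of the same construction and a similar number of genes gave a difference as low; their median was -0.06 and their lowest -0.10.

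**Figure D2:**
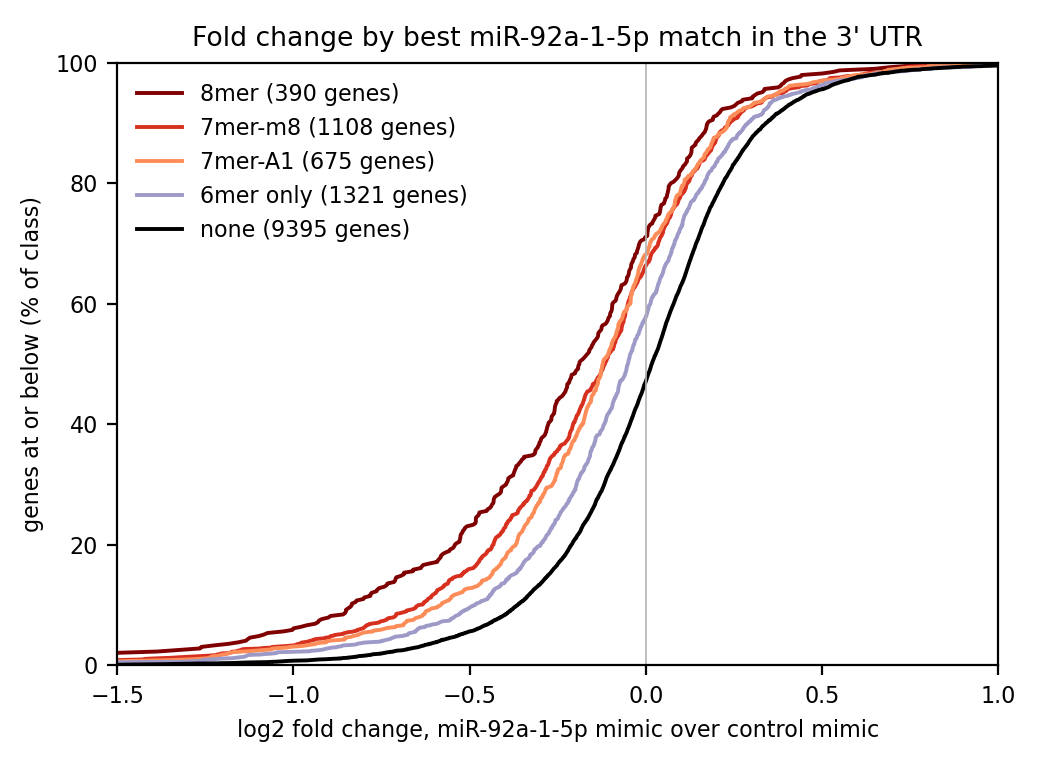
Cumulative distribution of the log2 fold change (mimic over control mimic) for genes grouped by their best match to the miR-92a-1-5p seed in the longest annotated 3′ UTR; each curve gives the percent of the class at or below the value, and genes beyond -1.5 and 1.0 lie off the axis. The medians run from -0.19 for genes with an 8mer to 0.02 for genes with no 6mer; those of the 7mer-m8 (-0.116) and 7mer-A1 (-0.122) classes lie close together.

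Among the lower genes 101 of 142 (71.1%) had a 7mer or 8mer match, against 16.3% of the genes called in neither direction (odds ratio 12.6, 95% interval 8.69 to 18.7; Fisher's exact test, adjusted p = 7.7e-46 over 16 such tests). Fisher's test treats genes as independent and takes no account of 3′ UTR length. The excess among the lower genes was 54.8 percentage points, and 0% of 1000 random seeds gave one as high (median 4.60, highest 36.8). Of the 60 higher genes with a 3′ UTR, 4 (6.67%) had a match. This share did not pass Fisher's test (adjusted p = 0.068), with an odds ratio of 0.367 (95% interval 0.0965 to 0.994). It was low among random seeds, of which 99.2% gave an excess at least as high. With the replicate block the shares were 42.6% of 934 lower genes and 6.72% of 625 higher genes against 15.3% of the rest, and the lower share among the higher genes passed the test (adjusted p = 6.6e-10). All 12 of the largest falls had at least 1 such match, and none of the 7 largest rises with an annotated 3′ UTR did.

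The 3′ UTR of SLC25A23 (1911 bases, minus strand) held 5 matches: 8mers at 6441832 to 6441839, 6441774 to 6441781 and 6441488 to 6441495, a 7mer-m8 at 6441389 to 6441395 and a 7mer-A1 at 6441904 to 6441910 of chromosome 19. The first and second of these 8mers lay in a near-repeat, CCTAGACTCCTATGCCCCAACCATTGGG and CCTAGACTCCTATGCCCCAACCACTGGG, in which the 8mer itself started at base 136 and base 194 of the UTR. PA2G4 (chromosome 12) had an 8mer at 56113089 to 56113096 and a 7mer-m8 at 56113025 to 56113031, and ACY1 an 8mer at 51989115 to 51989122 of chromosome 3, in a 3′ UTR of 273 bases. MYO1D had 7mer-m8 matches at 32494683 to 32494689 and 32494263 to 32494269 of chromosome 17. PUDP had a 7mer-m8 at 7050201 to 7050207 of chromosome X, 89 bases into the UTR, TMEM50A at 25360770 to 25360776 of chromosome 1, PPME1 at 74254693 to 74254699 of chromosome 11 and BNIP3L at 26410505 to 26410511 of chromosome 8. VCL, TGM2, DAG1 and GLTP each held a 7mer-A1. TMEM50A also held a miR-92a-3p 7mer-m8, DAG1 a miR-92a-3p 7mer-A1 and VCL a miR-92a-3p 7mer or 8mer match. For these genes the matches alone cannot separate the strands.

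Mitotic genes were higher with the mimic as a group. The 25 members of the mitosis and proliferation list were all on the positive side, with a median log2 fold change of 0.38 (camera adjusted p = 1.2e-13 over 30 lists; adjusted p = 0.70 with an estimated correlation). No member passed alone in edgeR's test over all genes, while 19 had an unadjusted p under 0.05, 17 passed when adjusted over the list alone, DESeq2 called 5 and limma-voom 0. With the replicate block 20 of the 25 rose and none fell, 23 when adjusted over the list alone. In the blocked fit the proliferation marker MKI67 rose by 0.55 ± 0.09 (SE), the mitotic kinase AURKA by 0.58 ± 0.09 and the cytokinesis motor KIF23 by 0.70 ± 0.12. MKI67 rose although it held a miR-92a-1-5p 7mer-A1 in the 3′ UTR and 6 matches in the coding sequence. MKI67 and TOP2A were named by the rule fixed beforehand as the most abundant members, whereas AURKA and KIF23, like the other blocked list members named below, were chosen after the values were seen. TOP2A had 599 ± 88.4 CPM in the control libraries and 772 ± 48.8 with the mimic. The list's median difference was 0.30, 0.34 and 0.54 in the pairs numbered 1, 2 and 3. Scramble 3 was lower on it than scramble 1 and 2, with a difference of -0.316, while miR92a 3 differed from miR92a 1 and 2 by -0.0648, and without scramble 3 the list median was 0.261. The DNA replication and G1/S list was also higher (median 0.22, 28 genes, adjusted p = 0.0014; 0.94 with an estimated correlation). None of its members passed over all genes without the block, while 2 rose when adjusted over the list alone. At an unadjusted p under 0.05 in edgeR's test 10 were higher and 2 lower, DESeq2 called 3 and limma-voom 0. With the block 9 rose, among them the E2F2 transcription factor (1.04 ± 0.12) and the ribonucleotide reductase subunit RRM2 (0.55 ± 0.09), and 2 fell, the cyclin D-dependent kinase CDK6 (-0.54 ± 0.09) and the uracil glycosylase UNG. Its call was lost without miR92a 3 (median 0.06, adjusted p = 0.13), and replicate 3 libraries were higher on it by 0.123 in the control and 0.336 in the mimic group.

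Growth-arrest genes moved apart. Of the 14 measured cell cycle inhibitors 1 fell, the antiproliferative gene BTG2, from 197 ± 20.4 to 126 ± 2.53 CPM (log2 fold change -0.64 ± 0.10, adjusted p = 0.022 by edgeR). Adjusted over the list alone, 5 fell and 2 rose. With the block the same numbers passed over all genes: CDKN1C (p57) fell by 0.52 ± 0.11 and CDKN2C (p18) rose by 0.58 ± 0.09. The list as a whole was not called (median -0.14, camera adjusted p = 0.24; median -0.242 without miR92a 2 and -0.223 without scramble 3).

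Among genes downstream of BCR-ABL1, the STAT5-induced signalling inhibitor SOCS2 fell from 49.9 ± 7.31 to 22.5 ± 1.33 CPM (-1.16 ± 0.15, adjusted p = 0.0076), the only one of 26 measured members of the STAT5 and ERK output list to pass, also when adjusted over the list alone. SOCS2 held 2 miR-92a-1-5p matches and 1 miR-92a-3p 7mer-m8 in its 3′ UTR. With the block 5 fell and none rose, including the kinase gene PIM2 (-0.53 ± 0.10) and the AP-1 gene FOSL1 (-0.79 ± 0.16). Of 28 kinases and transporters tied to imatinib response, the SRC-family kinase LYN fell (-0.55 ± 0.10, adjusted p = 0.046; 127 ± 11.7 to 87.7 ± 5.34 CPM), and 2 members fell when adjusted over the list alone. With the block 4 fell, including the receptor kinase AXL (-0.72 ± 0.14) and FYN, and 1 rose. ABL1 and BCR, named after their values were seen, had log2 fold changes of -0.12 ± 0.08 and -0.05 ± 0.10. Of 28 BCL2 family and apoptosis genes BNIP3L passed, also over the list alone. With the block 4 fell, among them the anti-apoptotic BCL2L1 (-0.52 ± 0.09) and the initiator caspase CASP8 (-0.39 ± 0.11), and BIRC5 rose by 0.30 ± 0.09. The best 3′ UTR match to miR-92a-1-5p was a 7mer-m8 in both BCL2L1 and BIRC5, and CASP8 had none. None of these 3 lists was called with all libraries (camera adjusted p = 0.29, 0.52 and 0.17), but without scramble 3 the STAT5 and ERK output list (median -0.13, adjusted p = 0.018) and the BCL2 family list (-0.10, 0.044) were. The median of the STAT5 and ERK output list was -0.06 without and 0.06 with the block, while camera's direction was down in both, and the unblocked median was 0.0657 without scramble 1 and 0.0236 without miR92a 1. The kinase list had a median of -0.04 and a mean of 0.01.

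The globin list and the erythroid regulator and membrane list were lower in the blocked fit. The heme and iron list was not called there (median -0.08, camera adjusted p = 0.19). Without the block no member of the globin, heme and iron, or erythroid regulator and membrane lists passed in edgeR; at an unadjusted p under 0.05 there were 0, 4 and 4, DESeq2 called 0, 1 and 3, and limma-voom 0 in each. With the block 8 of 28 erythroid regulator and membrane genes fell and none rose, and the list was called (median -0.19, camera adjusted p = 0.0068; adjusted p = 0.73 with an estimated correlation). The anion exchanger SLC4A1 fell by 0.81 ± 0.10, the membrane anchor ANK1 by 0.47 ± 0.08 and the transcription factor NFE2 by 0.39 ± 0.08, whereas GATA1, named after the fact, had 202 and 202 CPM. ANK1 held 3 7mer-m8 matches to miR-92a-1-5p. The 10 globins had a blocked median of -0.27 (adjusted p = 0.020; 0.80 with an estimated correlation), and HBZ fell by 0.41 ± 0.08. HBA1 and HBA2 also passed with the block, but these paralogs, like HBG1 and HBG2, share reads. The most abundant globins, HBE1 (4200 ± 1784 and 4032 ± 2301 CPM) and HBG2 (3394 ± 592 and 2979 ± 865 CPM), did not pass. Of 19 heme and iron genes 3 fell and 1 rose with the block: the transferrin receptor TFRC fell by 0.68 ± 0.07, from 1574 to 979 CPM, the ferritin light chain FTL fell by 0.34 ± 0.08, and the heavy chain FTH1 rose by 0.24 ± 0.07. Without the block the erythroid list was not called with all libraries (adjusted p = 0.13), and its median was -0.0047 (0.70) without scramble 3, while it was called without scramble 1 (-0.22, 0.0094), scramble 2 (-0.22, 0.025) and miR92a 3 (-0.28, 0.0012). Without miR92a 3 the globin list (-0.63, 0.0012) and the heme and iron list (-0.12, 0.0195) were called too, but neither median kept its sign: the globin median was 0.0922 without scramble 3 and 0.0344 without miR92a 2, and the heme and iron median 0.08 without scramble 3, 0.0114 without miR92a 1 and 0.00662 without miR92a 2. With the block the globin call was lost without pair 1 (camera adjusted p = 0.14) and pair 2 (0.27). The globin list's median difference was -0.36, -0.47 and -0.02 in the pairs numbered 1, 2 and 3. Replicate 3 libraries of both groups were higher than their replicate 1 and 2 libraries on the globin list (by 0.60 in the control and 0.76 in the mimic group), the heme and iron list (0.48 and 0.38) and the erythroid list (0.28 and 0.34).

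Metabolic genes changed in a few named members. PGK1, a glycolytic kinase, fell from 118 ± 4.47 to 65.1 ± 7.08 CPM (-0.83 ± 0.10, adjusted p = 0.0066) and hexokinase HK1 from 625 ± 52.9 to 385 ± 52.2 CPM (-0.69 ± 0.12, adjusted p = 0.031); they were the 2 of 26 glycolysis and hypoxia genes that passed, also over the list alone. With the block 6 fell, among them the glucose transporter SLC2A1 (-0.41 ± 0.08). INSIG1, the sterol-regulated anchor of the SREBP pathway, fell (-0.74 ± 0.14, adjusted p = 0.045), 1 of 24 cholesterol synthesis genes, or 2 when adjusted over the list alone. With the block 7 fell and none rose, among them MSMO1 by 0.58 ± 0.13, and the list was called (median -0.15, adjusted p = 0.011; 0.73 with an estimated correlation). Without the block the list was not called with all libraries (median -0.12, adjusted p = 0.128). It was called without scramble 1 (adjusted p = 0.0094), scramble 2 (0.012) and miR92a 3 (5.6e-05), but its median turned positive without scramble 3 (0.0313, 0.781) and miR92a 2 (0.0187, 0.520). Replicate 3 libraries were higher on this list by 0.31 and 0.42 in the control and mimic groups. PA2G4 was the only one of 24 MYC target and ribosome biogenesis genes to pass over all genes, while POLR1A (-0.33 ± 0.08) also passed over the list alone; with the block SRM and POLR1A also fell and NCL rose. The 52 ribosomal protein genes (median -0.03), the 13 mitochondrially encoded genes (-0.07) and the 29 nuclear oxidative phosphorylation genes (0.10) had no member that passed without the block in edgeR, DESeq2 or limma-voom, with 2, 0 and 1 members at an unadjusted p under 0.05. With the block 1 ribosomal protein gene, 0 mitochondrially encoded genes and 1 oxidative phosphorylation gene rose and none fell. These lists were not called, but without miR92a 3 the ribosomal protein list was (median -0.11, adjusted p = 0.0037), as was the glycolysis list (-0.14, 0.0061), and without miR92a 1 the oxidative phosphorylation list (0.11, 0.020). The ribosomal protein median was 0.0238 without miR92a 1 and the oxidative phosphorylation median -0.0142 without miR92a 3, so these directions reversed, as did that of the mitochondrially encoded genes without scramble 3 (0.0444) and miR92a 1 (0.0234), while their median was -0.193 without scramble 1. RPLP0 and MT-CO1, their most abundant members, had log2 fold changes of -0.18 ± 0.10 and -0.15 ± 0.09, and ATP5B had 0.06 ± 0.09. Of 26 autophagy and lysosome genes none passed in edgeR without the block (9 at an unadjusted p under 0.05, 2 in DESeq2 and 2 in limma-voom); over the list alone 3 rose and 1 fell. With the block 4 rose, among them LAMP1 (0.44 ± 0.09), and 2 fell, and CTSB and SQSTM1 had 0.05 ± 0.10 and 0.06 ± 0.13.

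Stress genes were partly higher. HSP90AA1, an HSP90 chaperone, rose from 1069 ± 143 to 1834 ± 31.1 CPM (0.78 ± 0.11, adjusted p = 0.013). It was the only one of 16 heat shock genes to pass over all genes, and 3 passed over the list alone. The list was higher (median 0.16, camera adjusted p = 0.030; adjusted p = 0.94 with an estimated correlation), and with the block 6 members rose, including DNAJA1 (0.46 ± 0.09) and HSPA1A (0.60 ± 0.11), and HSPA8 fell by 0.33 ± 0.08. The list's median difference was -0.02, 0.14 and 0.36 in the pairs numbered 1, 2 and 3. HSPA1A and HSPA1B are near-identical and share reads. The call was lost without scramble 3 (median 0.04, adjusted p = 0.57), miR92a 1 (0.18, 0.079) and miR92a 2 (0.14, 0.30), and replicate 3 libraries were lower on this list, with differences of -0.35 in the control and -0.16 in the mimic group. The integrated stress response list was higher too (25 genes, median 0.19, adjusted p = 0.023; 0.94 with an estimated correlation). No member passed alone in edgeR, DESeq2 or limma-voom, 3 had an unadjusted p under 0.05, and ATF4 had 244 ± 7.59 and 270 ± 9.27 CPM. With the block 4 rose, among them the amino-acid synthesis genes ASNS (0.50 ± 0.10) and PSAT1 (0.61 ± 0.14). Its median difference was -0.00553, 0.12 and 0.38 in the pairs numbered 1, 2 and 3, and replicate 3 libraries were lower on it, with differences of -0.23 in the control and -0.09 in the mimic group. That call was lost without scramble 3 (median 0.16, adjusted p = 0.16) and miR92a 2 (0.25, 0.23). Of 19 unfolded protein response genes PDIA4 alone passed, and the list was not called (adjusted p = 0.38; median 0.152 without scramble 1 and -0.0913 without scramble 3).

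Surface proteins and reported targets of the partner strand were lower. Of the 15 adhesion and surface genes 14 were on the negative side (median -0.19, camera adjusted p = 0.023; adjusted p = 0.94 with an estimated correlation), and the fibronectin receptor subunit ITGA5 passed alone, falling from 66.1 ± 14.8 to 30.6 ± 5.67 CPM (-1.16 ± 0.21, adjusted p = 0.039); over the list alone the tetraspanin CD151 also passed (-0.80 ± 0.16). With the block 3 members fell and 1 rose. ITGA5 has a miR-92a-1-5p 7mer at 54395357 to 54395363 of chromosome 12. Its 3′ UTR also matches the miR-92a-3p seed, so the matches alone cannot separate the strands. The list's call was lost without scramble 1 (median -0.14, adjusted p = 0.071), scramble 2 (-0.13, 0.084) and miR92a 3 (-0.11, 0.20), and the median was -0.280 without scramble 3. Replicate 3 libraries were lower on this list, with differences of -0.277 in the control and -0.133 in the mimic group. The 21 genes listed as reported targets of miR-92a-3p were lower as a group (median -0.22, adjusted p = 0.026; 0.70 with an estimated correlation; lost without miR92a 3, median -0.17, adjusted p = 0.10; median -0.407 without miR92a 2). Of these BTG2 and ITGA5 fell and MAP2K4 rose, and over the list alone 7 fell and 1 rose, the numbers that also passed over all genes with the block. Both BTG2 and MAP2K4 held miR-92a-3p 7mer matches in the 3′ UTR and no miR-92a-1-5p match there or in the coding sequence. BCL2L11, named after its value was seen, had -0.13 ± 0.09. In the microRNA machinery TNRC6B, a GW182 scaffold of the silencing complex, fell from 72.8 ± 6.43 to 42.5 ± 3.26 CPM (-0.81 ± 0.11, adjusted p = 0.013). It was the only one of 18 members to pass, also over the list alone, and has a miR-92a-1-5p 7mer-m8 at 40328126 to 40328132 of chromosome 22. TNRC6B also holds a miR-92a-3p 7mer-A1. The microRNA machinery list was not called (camera adjusted p = 0.54), with a median of 0.02 (-0.0156 without scramble 1, -0.0249 without miR92a 3) and a mean of -0.05.

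None of the inflammatory and lineage lists below was called. None of the 28 measured interferon-stimulated genes passed in edgeR, DESeq2 or limma-voom or had an unadjusted p under 0.05 (list median -0.07, adjusted p = 0.97), and IFITM1 had 156 ± 4.42 and 164 ± 14.0 CPM. ICAM1, an adhesion molecule induced by NF-kB, fell from 21.4 ± 0.936 to 12.3 ± 1.15 CPM (-0.85 ± 0.14, adjusted p = 0.026), 1 of 15 cytokine and NF-kB genes to pass without the block (list adjusted p = 0.98), and holds a miR-92a-1-5p 7mer-m8 at 10285768 to 10285774 of chromosome 19. ICAM1 also holds a miR-92a-3p 7mer-m8. With the block 2 members of the cytokine and NF-kB list rose and 2 fell, and the list median was 0.20. Without the block no member passed in edgeR, DESeq2 or limma-voom among 11 megakaryocyte and platelet, 17 granulocyte and monocyte, 10 stem and progenitor and 24 TGF-beta, SMAD and WNT genes, with 0, 0, 1 and 4 at an unadjusted p under 0.05 and list adjusted p of 0.96, 0.49, 0.49 and 0.65; over the list alone the progenitor transcription factor MECOM passed (-0.59 ± 0.16). MYB had 264 ± 59.8 and 241 ± 56.4 CPM and MS4A3 449 ± 225 and 416 ± 252 CPM. Replicate 3 libraries were lower on the stem and progenitor list, with differences of -0.54 and -0.51. With the block 1, 2, 1 and 4 members of these lists passed, among them TUBB1, LYZ and MECOM, which fell, and in the TGF-beta, SMAD and WNT list they passed in both directions. Since 1639 of all 14543 tested genes passed with the block, these few members do not set the lists apart. The medians of uncalled lists were not stable: that of the granulocyte and monocyte list was -0.17, and -0.667 with the block and pair 2 left out, that of the stem and progenitor list -0.17, and -0.365 without scramble 3 and 0.0230 without miR92a 3, and that of the cytokine list -0.327 without miR92a 2. Medians turned positive without scramble 1 (0.153) and miR92a 3 (0.108) for the megakaryocyte list, and without scramble 2 (0.0240) and miR92a 3 (0.0611) for the interferon list. The lymphoid median was 0.01 (6 genes), and 0.435 without miR92a 2 (7 genes). The megakaryocyte list had a median of -0.10 and the cytokine list one of 0.04, while camera's direction was up and down. Of markers of other cell types, CD3G had 5.96 ± 0.306 and 4.12 ± 0.066 CPM and EPCAM 151 ± 22.4 and 167 ± 7.64 CPM, and neither the 6 lymphoid nor the 8 fibroblast, epithelial and endothelial genes measured held a member that passed in those tools without the block (1 each at an unadjusted p under 0.05; list adjusted p = 0.97 for each). Over the list alone COL1A1 passed (-1.68 ± 0.41), and with the block it was the 1 member of these 2 lists to pass.

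The calls of single list members were less stable than the largest changes. LYN missed the threshold without any library (adjusted p 0.0591 to 0.185). BTG2 (0.0504 to 0.109), ICAM1 (0.0511 to 0.15) and ITGA5 (0.0928 to 0.136) missed it without each library except scramble 3, and INSIG1 without each except miR92a 3 (0.0562 to 0.172). HK1 missed it without scramble 1, scramble 2, miR92a 1 or miR92a 2 (0.0942 to 0.132) and HSP90AA1 without scramble 2, miR92a 1 or miR92a 2 (0.0548 to 0.0763). TNRC6B missed it without scramble 1 (0.0651) or miR92a 2 (0.0843), SOCS2 without miR92a 1 (0.0511) and PGK1 without miR92a 2 (0.0543). All kept their direction, as their non-overlapping values require. PGK1, LYN, BTG2 and INSIG1 fell without a 7mer or 8mer match to miR-92a-1-5p in the 3′ UTR. SOCS2, ITGA5, ICAM1, HK1 and TNRC6B fell and held such a match.

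**Figure D3:**
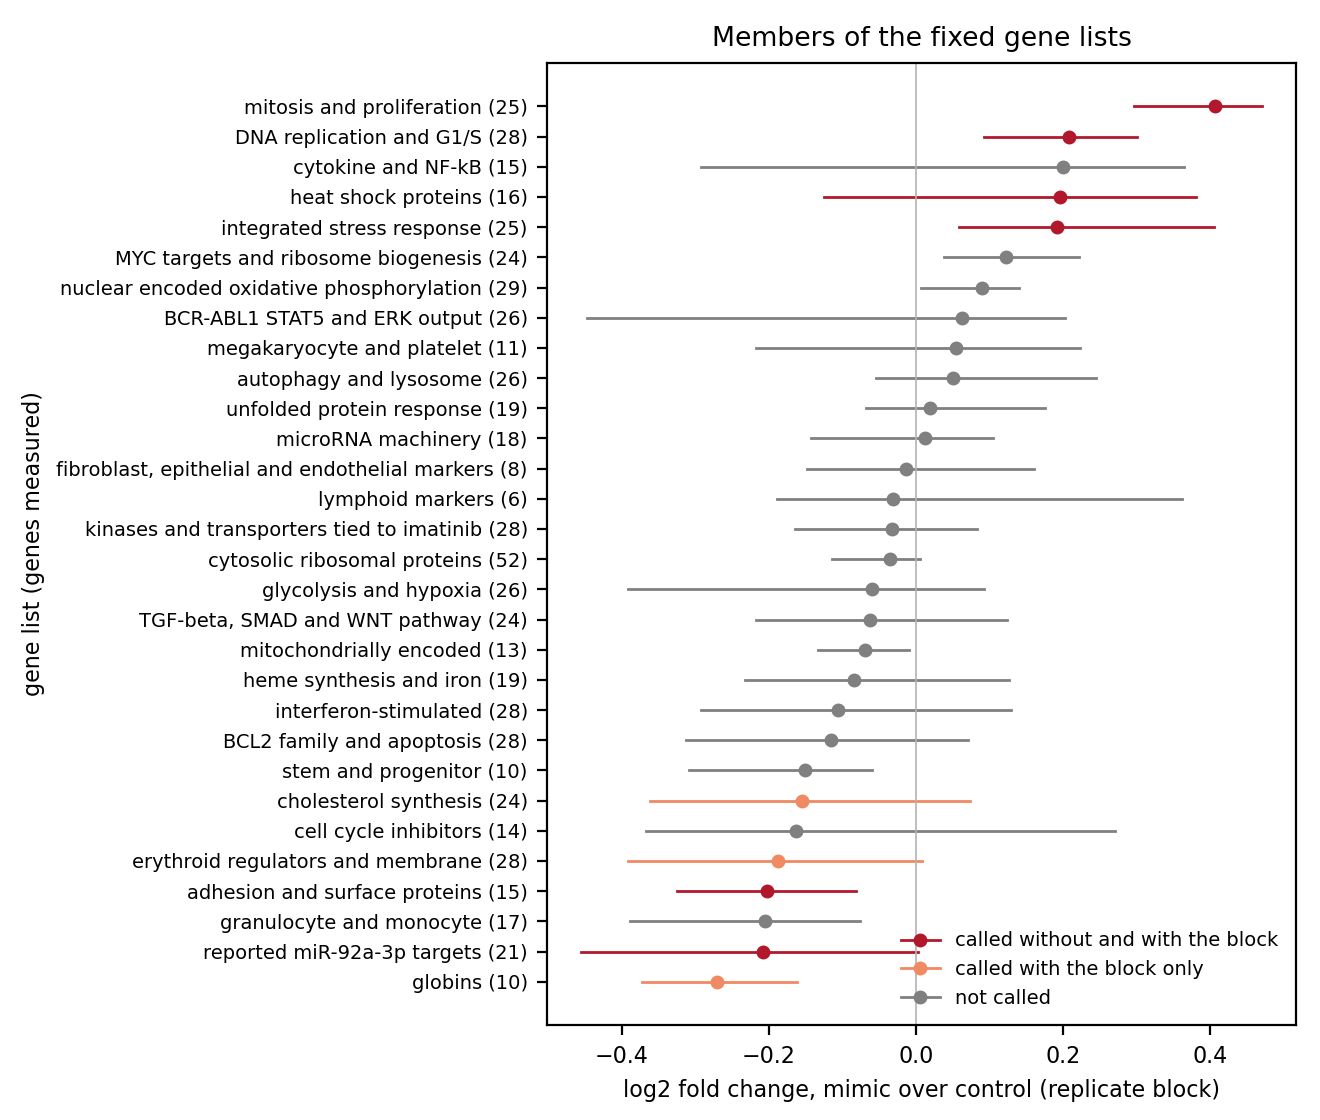
Median (point) and interquartile range (line) of the members' log2 fold changes, mimic over control mimic, from the fit with the replicate number as a block, for each of the 30 gene lists; the number of genes measured is in parentheses. Lists in dark red were called without and with the block and lists in orange with the block alone, at camera's preset correlation; the mitosis and proliferation list has the highest median (0.41) and the globin list the lowest (-0.27).

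Genes with a match to the seed of the partner strand miR-92a-3p differed less. Their median log2 fold change was -0.07 (2591 genes) against 0.00 for genes without one, a difference of -0.08 (camera p = 0.019; p = 0.13 with an estimated correlation). Matched on 3′ UTR length the difference was -0.02 (camera at the preset correlation, p = 0.50), and 29.1% of 1000 random seeds gave one as low. It was 0.00, -0.06 and -0.11 in miR92a 1, 2 and 3. Of the 142 lower genes 31.0% had a miR-92a-3p match, against 19.9% of the genes called in neither direction (Fisher's exact test, adjusted p = 0.0033), and 8.5% of random seeds gave an excess as high. With the block the shares were 27.1% and 19.96% (adjusted p = 1.1e-06), and 26.4% of random seeds gave an excess as high. Of the 60 higher genes 30% had one (adjusted p = 0.0895), with 4.3% of random seeds as high, while with the block the share among higher genes was 12.3%. At the preset correlation the call was lost without scramble 3 (-0.07, p = 0.053) and without miR92a 3 (-0.04, p = 0.18).

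The replicate 3 libraries stood apart in both groups. On the first principal component, which held 42.5% of the variance, scramble 3 lay at 15.3 and scramble 1 and 2 at 3.94 and 4.21, while miR92a 1, 2 and 3 were spread over -16.0, -7.74 and 0.229. On the second (37.6%) miR92a 3 lay at 17.9 and miR92a 1 and 2 at -2.18 and 0.571, and scramble 3 lay at 2.83 and scramble 1 and 2 at -10.0 and -9.08. Scramble 1 and scramble 2 differed from each other by a chi-square per gene of 4.83, where 1 is sampling noise, and from scramble 3 by 48.4 and 43.0. The corresponding values were 1.81 for miR92a 1 against miR92a 2, at the low depth of miR92a 1, and 43.8 for miR92a 2 against miR92a 3. Each library was counted as a replicate because the labels call them biological replicates, without saying what was repeated; the chi-square does not tell separate cultures from repeat preparations of 1 culture.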

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

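The data cover 1 cell line, 1 mimic dose and 1 time point, with 3 libraries per group, of which 1 is 36.0-fold shallower than the median of the others, and the counts of changed genes depended strongly on the model. DESeq2 called 248 lower and 139 higher genes, the test against a fold of 1.2 called 64 and 17, and the replicate block called 975 and 664. The block with pair 1, 2 or 3 left out gave 751 and 486, 549 and 285, and 866 and 554. Replicates 1 and 2 alone gave 1296 and 938, and a batch term for replicate 3 gave 1262 and 976. Thinning to the lowest depth gave 102 and 38 without the block and 262 and 154 with it. With 1 library left out the counts ran from 56 to 148 lower and from 14 to 53 higher. No measured gene among the 205 changed direction in any setting, which their non-overlapping values largely fixed in advance. Of the 30 named genes past the threshold 12 passed in every alternative run. The highest adjusted p over these runs was 0.649 for ICAM1, whose weakest log2 fold change was -0.474. For MAP2K4 the adjusted p reached 0.499 and the weakest log2 fold change was 0.508. Of the 30 lists 6 were called without and 9 with the block, 11 with the block and pair 3 left out, 10 in replicates 1 and 2 alone, 0 with the correlation estimated and 0 by fry. The latter 2 had 2 and 3 lists at an unadjusted p under 0.05, and fry's mixed test, which ignores direction, called 12. With the correlation estimated, camera's adjusted p of the reported miR-92a-3p target list rose from 0.026 to 0.70. Its estimated correlation, 0.0085, lay below the preset 0.01, so the lost call of this list does not show that its members vary together. The other lists called without or with the block had estimated correlations of 0.134 to 0.595 in the fit without it, above the preset value. That of the mitosis and proliferation list was 0.355, so members that vary together stay open for these lists. The block added the globin, erythroid and cholesterol lists and changed no other list call. The median of the globin list ran from -0.631 to 0.0922 with 1 library left out and was reversed without scramble 3 (0.0922) and miR92a 2 (0.03). That of the cholesterol list ran from -0.398 to 0.0313 and was reversed without the same libraries (0.0313 and 0.02). That of the erythroid list ran from -0.281 to -0.0047. The miR-92a-3p site difference was -0.0758 with the correlation estimated, -0.0218 matched on 3′ UTR length, -0.0315 with the block and pair 3 left out, -0.0506 in replicates 1 and 2, and -0.0894 to -0.0411 with 1 library left out. The miR-92a-1-5p site difference ran from -0.15 to -0.13 with 1 library left out and passed in every setting. The cause of the low depth of miR92a 1 and of the distance of the replicate 3 libraries was not tested.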

Other observations

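Genes with a miR-92a-1-5p match in the coding sequence and no 6mer in the 3′ UTR were also lower with the mimic. Their median log2 fold change was -0.05 (1810 genes), against 0.03 for the 7585 genes without such a match.

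The tests of 3′ UTR length and of length with GC content for miR-92a-3p sites, of shares among called genes against random seeds, and camera's tests on the matched genes were chosen only after the result was seen. Genes with a miR-92a-3p site were lower by a difference of -0.08. Co-occurring miR-92a-1-5p matches were argued against only as the sole cause, since genes without one still differed by -0.0705 (camera at the preset correlation, p = 0.0151, or 0.118 with an estimated correlation). Matched on 3′ UTR length as well, these genes differed by -0.0308 (95% bootstrap interval -0.0542 to -0.00467, camera at the preset correlation p = 0.246). Over all genes with a 3′ UTR the random seeds had a median difference of -0.0626. A difference near -0.07 is thus usual for a seed of this size, and a part played by co-occurring matches was not excluded. Activity of the miR-92a-3p strand was argued against as the source of the -0.08 difference because 29.1% of random seeds gave one as low. Lower genes held more miR-92a-3p matches (31.0% against 19.9%), as did 8.5% of random seeds to that degree, so a small effect was not excluded. Longer 3′ UTRs stay open: matching on length left -0.0218, with a 95% bootstrap interval over genes of -0.0360 to -0.0040 but p = 0.496 by camera at the preset correlation, and length together with GC content may account for the pattern, since matching on both left -0.0106 (-0.0276 to 0.00618).

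All 3 tests of the mitosis and proliferation list were chosen only after the result was seen. The list had a blocked median of 0.41. The shallow library was argued against only as the sole source, since the median was 0.46 without pair 1. The same holds for the pair numbered 3, since the median was 0.32 without that pair. The pair medians of 0.30, 0.34 and 0.54 were already known, so these tests could hardly have come out otherwise. They do not exclude a part played by either. The list's estimated correlation between members was 0.355 in the fit without the block, above the preset 0.01. Members that vary together between cultures could give such a shift and stay open. Camera with an estimated correlation (blocked adjusted p = 0.73) could not decide this. In that setting 0 of the 30 lists had even an unadjusted p under 0.05.

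The tests of coding matches were chosen before their result was seen, except camera's tests on the matched genes. Longer coding sequences were argued against, since the difference was -0.0721 after matching on length, and base composition was argued against, since it was -0.0867 after matching on length and GC content (camera at the preset correlation, p = 0.00211 and 0.00101). Activity of the mimic strand at coding sites is a candidate explanation and stays open, as neither binding nor translation was measured. The difference before matching was -0.0809, and 0 of 1000 random seeds gave one as low, but the lowest came close, at -0.0783. Coding matches to miR-92a-3p among the same genes gave -0.0713, and 10.1% of random seeds gave one as low.

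The splits of the libraries into other groups are too few for a share under 0.05. Without the block 1 of 10 splits, the real one, reached 205 called genes (highest other 77), 6 of 10 reached the 6 called lists (highest other 17), and 1 of 10 reached a miR-92a-1-5p site difference of 0.135 in size (highest other 0.0789). With the block 1 of 4 splits reached 1639 genes (highest other 1) and 1 of 4 reached 9 lists (highest other 6). The number of lists called without the block therefore did not set the real grouping apart, whereas the gene counts and the site difference were largest in it.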
